A study of Oryza sativa Japonica Group with 3 samples.

How the data were processed

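Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out by the submitters on whole rice seedlings of the japonica cultivar Nipponbare. Per the labels' protocols, plants grew for 14 days at 28 °C in short days of 10 h light and 14 h dark, and a pool of 20 plants was frozen at zeitgeber time 14 (ZT14), which lies in the dark part of such a day. Chromatin was fixed with formaldehyde. The LUX library came from plants carrying a genomic OsLUX construct with a c-MYC tag, precipitated with an anti-MYC antibody. The ELF3 library came from wild-type plants and a custom antibody. The third library was input DNA of wild-type plants. Each group holds 1 library, so no spread between replicates could be measured and no test across conditions was made. The series' design text also names an elf3-1 line, which was not analysed here.

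The build IRGSP-1.0 and the tools BWA, MACS2 and deepTools are named, without their roles, per the submitters' processing notes. The aligner's version and settings and the filter on reads are not given in the sources used here. Peaks were called with MACS 2.2.7.1, each ChIP library against the 1 input library, per the file headers, with sub-peak summits, a q-value threshold of 0.05 and 1 tag kept per position. Each library was called in 2 ways that differ in the lower bound of the model fold, 2 or 5, with 50 as the upper bound in both. That bound changed the fragment length to which tags were extended. For LUX it was 122 bp with the lower bound of 2 and 76 bp with the lower bound of 5, beside a tag size of 75 bp. For ELF3 it was 202 and 197 bp. The call with the lower bound of 2 was taken as the main one for both libraries, because the LUX fragment length in the other call nearly equals the tag size, and the other call was used as an alternative. This choice was made after the headers and the numbers of peaks had been seen, and before any test.

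The deposited pileup is the coverage signal at a summit, in extended tags, and the larger library was scaled towards the smaller, per the file headers. The deposited fold enrichment is the ratio of the pileup plus 1 to the local background plus 1. The deposited −log10 p and −log10 q values are those of the peak caller. Positions are as deposited, on IRGSP-1.0 and counted from 1. Dividing the pileup by the scale factor, 0.734 for LUX and 0.806 for ELF3, gave whole tags to within 0.01 for every summit of all tables. The local background was recovered from the pileup and the fold enrichment. Its lowest values equalled the genome-wide background, 8.60 scaled tags for LUX and 14.2 for ELF3, so a local dip of the input could not raise a fold enrichment. A region was counted as at the genome-wide background where the recovered background lay within 0.01 scaled tags of it. The caller's effective genome size was 210 Mb, whereas the furthest peaks on the 12 chromosomes span 367.6 Mb. Over that span the genome-wide background would be 4.91 and 8.13 scaled tags, so fold enrichments at genome-wide background may be low estimates. How much of the span can hold tags was not measured.

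Before filtering, per the file headers, the LUX library held 23370643 tags, the ELF3 library 24294237 and the input 15833936. After removal of duplicates, 20173598, 18357646 and 14797701 tags were left, and the duplicate rates were 14%, 24% and 7%. Intervals on tags are exact 95% Poisson intervals and those on shares are exact 95% Clopper-Pearson intervals. They cover counting error only, without the input's own error and without any variation between plants or precipitations.

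Lines with the same start and end were joined to 1 region, represented by its summit of highest fold enrichment. Regions of the libraries were compared by an overlap of at least 1 bp. The number of overlapping LUX regions was set against 10000 random placements of the LUX regions on their own chromosomes, with the furthest peak of any table as the end of a chromosome. The smallest p these placements can give is 1e-04. Medians within a list were compared by two-sided permutation of the overlap label among regions with 100000 resamples, whose smallest p is 1e-05. Regions are not replicates, and such p-values describe these lists alone. In all, 10 p-values over the regions or chromosomes of the lists were adjusted together by the Benjamini-Hochberg method. Of these, only that of the ELF3 fold enrichment with and without LUX was in the plan fixed before the data were examined. The comparisons of summit distance and of ELF3 regions of like width were chosen after the overlap had been seen. The 4 correlations within sets of shared regions, a split made after the pooled relation had been seen, were adjusted separately, as were 4 tests on regions joined within 5 kb. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

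Both main tests were tested on simulated data. For the overlap of 177 LUX regions with ELF3 regions, 100 simulations with 15 planted overlaps all gave p below 0.05, as did 7% of 100 simulations with 0 planted. For the median fold of the 824 ELF3 regions, a fold raised 2 times in 15 regions was found in 100% of 100 simulations, and 5% of those without a difference passed. Simulated LUX regions were placed singly and at random, and simulated folds were shuffled among regions, as in the tests themselves. The simulations therefore check the calculations only and leave out the clustering of regions in the lists.

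The named regions follow a rule fixed before the data were examined. It takes the 15 regions of highest fold enrichment in each library and the LUX regions overlapping ELF3, up to 20. The widest ELF3 region, the ELF3 domains and the loci of several LUX regions given by position were chosen after their values were seen. For the count of 0 among the 7 LUX regions of high −log10 q, the limit given is 3 regions of the total, a rough bound at so small a number. The plan also held shares in promoters, lists of clock, flowering and light signalling genes, groups of gene products and the LUX binding motif. Those parts were not analysed here, because the gene table at hand belongs to the assembly ASM3414082v1, whose coordinates differ from those of IRGSP-1.0, and no IRGSP-1.0 sequence or annotation was used here. Regions are therefore given by position and are not paired with genes. Alternatives for the overlap, the threshold and the peak call were also fixed before the data were examined.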

Results

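The series examined where 2 proteins of the rice evening complex, LUX and ELF3, sit on chromatin in short-day seedlings at ZT14. The evening complex is a transcriptional repressor within the plant circadian clock that acts around dusk and at night. LUX is its MYB-type DNA-binding member and ELF3 its scaffold protein. The data collected are peak lists of 1 LUX and 1 ELF3 ChIP-seq library, both called by the submitters against 1 input library. They rest on 20173598 LUX tags, 18357646 ELF3 tags and 14797701 input tags after filtering. With 1 library per group there is no replicate check, each value describes these libraries, and intervals cover counting error only. Fold enrichments are those of the authors' peak caller. No control for the specificity of either antibody was analysed here. All positions are on IRGSP-1.0.

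ELF3 was enriched at 824 regions on all 12 chromosomes, and 53 of them had a fold enrichment of 10 or more over input. The region of highest enrichment lay on chromosome 8 from 9094390 to 9098557, with 17.95-fold enrichment (95% Poisson interval 16.1 to 20.0, 338 tags at the summit). The second lay on chromosome 9 from 16458040 to 16460898, with 17.8-fold (15.9 to 19.8). Chromosome 1 held 5 of the 15 strongest regions. Those from 10009375 to 10013248 and from 8952512 to 8957350 were enriched 16.9-fold and 16.8-fold, and those from 3092715 to 3094248 and from 4341515 to 4343971 both 16.3-fold. The region from 17150715 to 17153853 was enriched 13.5-fold. Chromosome 3 held regions from 32429742 to 32432248 with 16.1-fold, from 9768675 to 9769454 with 15.4-fold and from 24241094 to 24244080 with 15.3-fold enrichment. The region on chromosome 9 from 6398398 to 6401402 was enriched 15.1-fold, that on chromosome 11 from 7657688 to 7661994 was enriched 14.9-fold and that on chromosome 10 from 22072252 to 22076145 was enriched 14.7-fold. Chromosome 2 completed the group with 14.4-fold from 19614897 to 19617131 and 14.0-fold from 5469582 to 5472740.

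Most ELF3 regions were weaker and narrower than these. The median fold enrichment over the 824 regions was 3.13 and the median width 410 bp, and 370 regions (44.9%) had a −log10 q of 10 or more. A single summit was resolved in most regions, whereas 240 regions (29.1%) held several, and 41 regions were 2 kb or wider. The widest, on chromosome 8 from 4623482 to 4629550, spanned 6069 bp with 10 summits. Many ELF3 regions lay close together, and 487 of them (59.1%) had another ELF3 region within 5 kb. Joined at that distance they formed 502 domains, of which 86 held 3 or more regions. The longest domain covered 12151 bp on chromosome 3 from 3733380 to 3745530 with 5 regions, followed by 11859 bp on chromosome 9 from 20884929 to 20896787 with 6 regions and 11622 bp on chromosome 1 from 4334362 to 4345983 with 8 regions.

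The LUX list was shorter. It held 177 regions with a median width of 189 bp and a median fold enrichment of 3.06, and 7 of them (3.95%) reached a −log10 q of 10. The strongest region, on chromosome 6 from 20110047 to 20110636, was enriched 5.36-fold (4.27 to 6.65, 80 tags at the summit). It was followed by chromosome 10 from 4964257 to 4964569 with 4.84-fold (3.74 to 6.18), chromosome 1 from 19823093 to 19823249 with 4.77-fold (3.67 to 6.09) and chromosome 12 from 4639248 to 4639527 with 4.61-fold (3.54 to 5.92). Neighbouring regions on chromosome 6, from 13890844 to 13891174 and from 13889775 to 13890329, were enriched 4.52-fold and 4.38-fold. Chromosome 8 contributed 9912799 to 9912972 with 4.43-fold and 11435913 to 11436195 with 4.16-fold enrichment. Chromosome 11 contributed 7659489 to 7659665 with 4.38-fold and 11958550 to 11959306 with 4.25-fold. On chromosome 9, the regions from 13469564 to 13469944 and from 2392906 to 2393068 were enriched 4.28-fold and 4.23-fold. The other three were on chromosome 7 from 6318279 to 6318698 with 4.31-fold, chromosome 3 from 15158880 to 15159104 with 4.23-fold and chromosome 10 from 8839112 to 8839354 with 4.16-fold. The counting intervals of the 15 regions overlap one another, so their order is not resolved at this depth.

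The number of LUX regions depended on how the peaks were called. With the other fragment length of the submitters, 91 LUX regions were called in place of 177, and 72 of the 177 were found again. For ELF3 the corresponding numbers were 843 in place of 824, with 812 found again. All 15 strongest regions of each library were found in both calls, and 7 of the 15 LUX regions and 14 of the 15 ELF3 regions were also among the 15 strongest of the other call.

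The libraries are compared because both proteins belong to the same complex. LUX and ELF3 regions overlapped at 15 places, and these were mostly among the strongest ELF3 regions. The 15 shared LUX regions made up 8.47% of the LUX list (95% interval 4.82 to 13.6%) and lay wholly inside 15 separate ELF3 regions, 1.82% of the ELF3 list (1.02 to 2.98%). In 10000 random placements of the LUX regions the mean overlap was 0.350 and the highest 4, so the observed number was above every placement (one-sided permutation of positions, p = 1e-04, the smallest possible). Placements were uniform over the chromosomes, including any stretches that cannot hold tags. The p-value therefore measures departure from uniform placement alone. Of the 7 LUX regions with a −log10 q of 10 or more, 0 overlapped an ELF3 region, which allows a share of up to 42.9%. With the other peak call 4 of 91 LUX regions overlapped ELF3, also above the placements (one-sided permutation of positions, p = 1e-04), and 11 of the 15 shared LUX regions (73.3%) were absent from that call. Of the 162 LUX regions without ELF3, 94 (58.0%) were absent from it, a share that Fisher's exact test did not separate (p = 0.286, adjusted p = 0.357).

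Among the 15 strongest ELF3 regions, 8 held a LUX region (53.3%, 95% interval 26.6 to 78.7%). These were the regions on chromosome 8 at 9094390, on chromosome 1 at 10009375, 8952512 and 4341515, on chromosome 3 at 32429742, on chromosome 9 at 6398398, on chromosome 11 at 7657688 and on chromosome 10 at 22072252, by their start. LUX enrichment in them ranged from 2.85-fold to 4.38-fold. The other seven of the 15 held none, among them the second strongest, on chromosome 9 at 16458040, whose nearest LUX region was 1095687 bp away. In the other peak call 3 of the 15 strongest held a LUX region. Among the next 85 ELF3 regions by enrichment, 6 held a LUX region (7.06%, 2.63 to 14.7%). Their starts were 18616445 on chromosome 12, 39074688 on chromosome 1, 20890411 and 20649943 on chromosome 9, 4623482 on chromosome 8 and 3742960 on chromosome 3. Of the following 200 regions 1 held LUX (0.50%, 0.0127 to 2.75%), on chromosome 11 at 20188403, and of the remaining 524 it was 0 (0 to 0.702%).

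**Figure D1:**
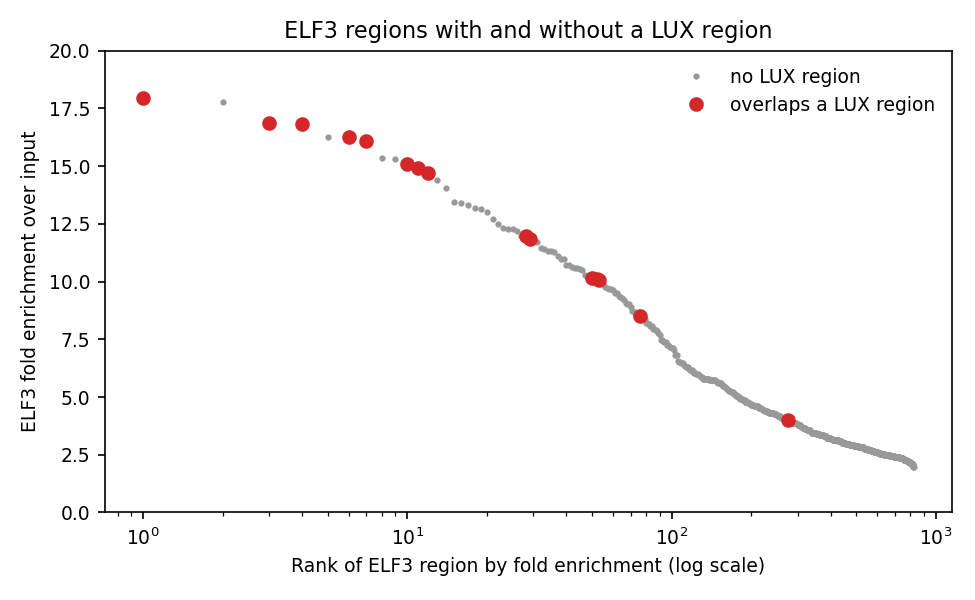
Each point is 1 of the 824 ELF3 regions, with its rank by fold enrichment on the log-scaled x axis and its fold enrichment over input on the y axis. Red points overlap a LUX region: 8 lie among the 15 strongest, 6 among the next 85 and 1 further down.

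ELF3 regions with LUX were enriched 14.7-fold at the median (n = 15 regions), and those without LUX 3.13-fold (n = 809 regions). The difference of 11.6 was larger than in all 100000 permutations of the overlap label (two-sided permutation p = 1e-05, adjusted p = 5e-05, 10 tests). They were also wider, with medians of 3005 and 401 bp (permutation p = 1e-05, adjusted p = 5e-05). Against ELF3 regions of like width without LUX, within 20% of the width, the median enrichment was 14.7-fold with LUX and 10.1-fold without (95% of 10000 draws from 8.37 to 11.4). This comparison was chosen after the data were seen, and the fewest regions available for a match was 1. The draws therefore reuse a few wide regions, and their range leaves out the spread between regions.

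Within the shared regions LUX lay at the ELF3 maximum, a comparison chosen after the overlap had been seen. The distance between the highest LUX and the highest ELF3 summit had a median of 42 bp and was 100 bp or less in 13 of the 15 regions. Random positions in the same ELF3 regions gave a median of 751 bp (95% of 10000 draws from 384 to 1258 bp; one-sided permutation of positions, p = 1e-04, the smallest possible). On chromosome 9 at 6398941 the summits coincided to the base, and on chromosome 8 they lay 11 bp apart in an ELF3 region of 4168 bp. The exceptions were the 6069 bp region on chromosome 8, with 1242 bp, and the region on chromosome 11 at 20188403, with 390 bp.

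Across the 15 shared regions, LUX enrichment was higher where ELF3 enrichment was higher. Pearson's r was 0.68 (permutation p = 0.00523, adjusted p = 0.0174) and Spearman's rho 0.66 (permutation p = 0.00892, adjusted p = 0.0223). Without the 2 regions farthest from the median ELF3 enrichment, r was 0.62 over 13 regions (permutation p = 0.0259). Both enrichments were computed against the same input, and regions of 1 library pair are not replicates. In sets of 8 and 7 regions, split after the relation had been seen, it was not detectable at that number of regions. In the 8 shared regions among the 15 strongest ELF3 regions the median LUX enrichment was 3.58, and in the other seven it was 2.79, a difference that was not tested. Within the 8 regions r was −0.19 (exact permutation p = 0.666, adjusted p = 0.703 over 4 tests) and rho −0.17 (exact permutation p = 0.703, adjusted p = 0.703). Within the 7 regions r was 0.47 (exact permutation p = 0.313, adjusted p = 0.703) and rho 0.39 (exact permutation p = 0.396, adjusted p = 0.703).

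**Figure D2:**
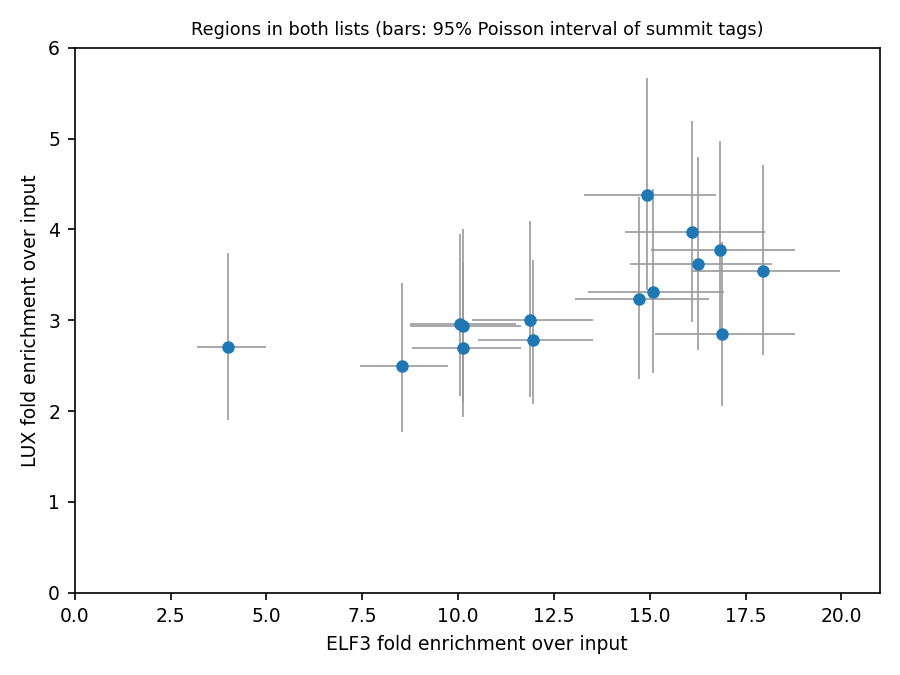
Each point is 1 of the 15 regions in both lists, with ELF3 fold enrichment on the x axis and LUX fold enrichment on the y axis, and bars give 95% Poisson intervals of the tags at each summit. LUX enrichment runs from 2.49 to 4.38 and ELF3 enrichment from 4.01 to 17.95, and the LUX intervals overlap widely.

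The remaining 162 LUX regions overlapped no ELF3 region. Their median enrichment of 3.06 differed by 0.05 from the 3.01 of the 15 shared regions, which the permutation test did not separate (p = 0.766, adjusted p = 0.766). Of the 15 strongest LUX regions, 14 were of this kind, and the 15 lay in 14 loci, 13 of them without ELF3. Joined within 5 kb, the 162 regions formed 115 loci. Of the 162 regions, 75 (46.3%) had such a neighbour, at 81 to 1462 bp, and the next distance between regions of this kind was 90101 bp. The caller can divide an enriched locus into several narrow regions, so regions of a locus are not independent. By locus, the median of the highest LUX enrichment was 3.06 without ELF3 (n = 115 loci) and 3.01 with it (n = 15 loci; permutation p = 0.822, adjusted p = 0.822 over 4 tests). Of the 15 shared regions, 0 had another LUX region within 5 kb. Loci of 3 or more regions numbered 13 and spanned 977 to 3412 bp. The largest held 5 regions on chromosome 12 from 1767867 to 1771278, and others of 4 regions stood on chromosome 8 from 9910994 to 9912972, chromosome 10 from 8838389 to 8840377, chromosome 6 from 16221863 to 16223503 and chromosome 2 from 19044563 to 19046536. The local input background was within 0.01 scaled tags of its genome-wide value in 64 of the 162 regions (39.5%) and in 9 of the 15 shared regions (60.0%), which Fisher's exact test did not separate (two-sided p = 0.170, adjusted p = 0.270). By locus it was 52 of 115 and 9 of 15 (Fisher's exact test, two-sided p = 0.410, adjusted p = 0.547).

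Along the genome, ELF3 regions were densest on chromosome 3, with 3.40 per Mb, and sparsest on chromosome 11, with 1.07 per Mb. LUX regions were densest on chromosome 8, with 0.926 per Mb, and sparsest on chromosomes 4 and 7, with 0.169 per Mb on each. With regions joined within 5 kb, ELF3 domains were sparsest on chromosome 12, with 0.709 per Mb, and densest on chromosome 3, with 2.27. Over the 12 chromosomes no relation of the densities of regions passed the test (Pearson r = −0.41, permutation p = 0.189, adjusted p = 0.270; Spearman rho = −0.49, permutation p = 0.112, adjusted p = 0.224). Without the 2 chromosomes farthest from the median ELF3 density, r was −0.49 (permutation p = 0.149). With joined regions r was −0.37 (permutation p = 0.238, adjusted p = 0.477) and rho −0.52 (permutation p = 0.0895, adjusted p = 0.358).

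**Figure D3:**
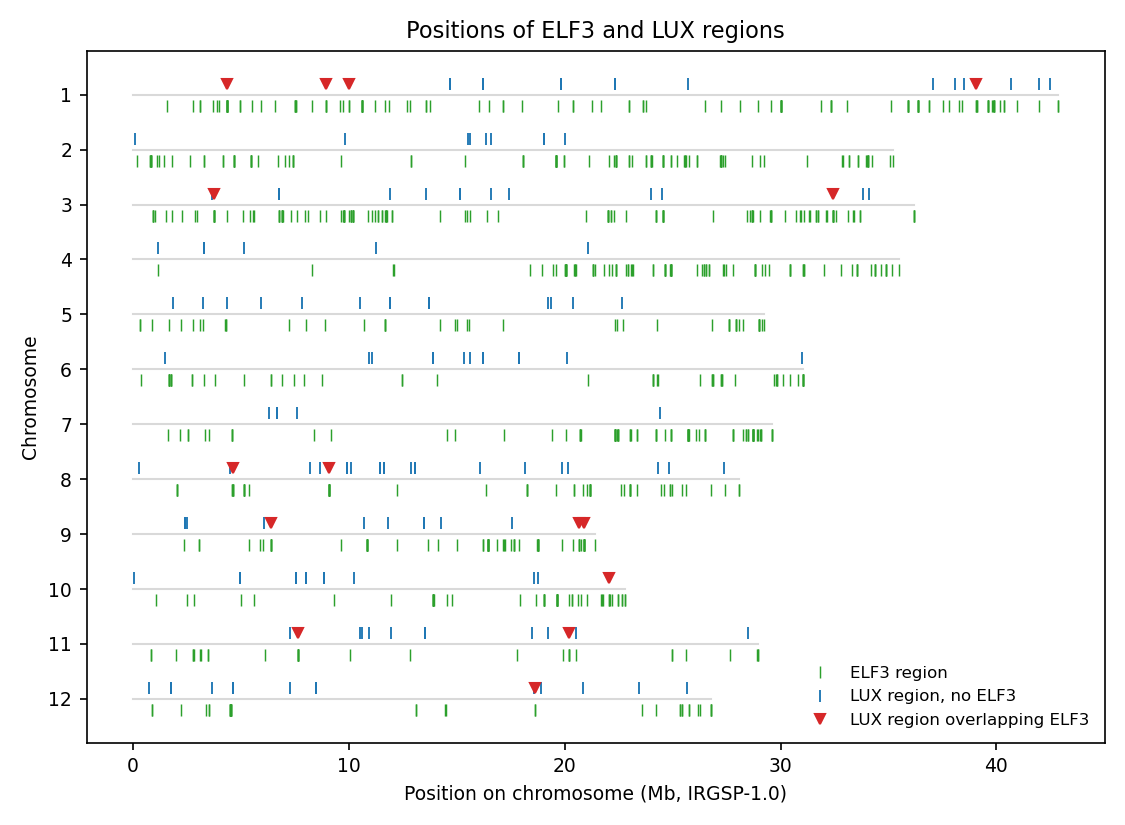
Positions in Mb along the 12 chromosomes, with ELF3 regions as green ticks below each line, LUX regions without ELF3 as blue ticks above it and the 15 LUX regions overlapping ELF3 as red triangles. Shared regions lie on 7 chromosomes, 4 of them on chromosome 1, and 162 LUX regions lie apart from ELF3.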

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

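All tests of explanations in this part were chosen after the result was seen. Signal outside the main peak lists was found in the submitters' other call. It held 10 LUX regions that overlap no region of the main LUX list, with fold enrichments up to 4.31 and 0 of them overlapping an ELF3 region. It also held 30 ELF3 regions absent from the main ELF3 list, with fold enrichments up to 3.10.

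The first pattern followed up is that LUX regions sit at the strongest ELF3 regions. Chance capture by wide ELF3 regions is argued against by the summit distance of 42 bp, below 95% of random positions in the same regions (384 to 1258 bp). Width alone stays open. The median enrichment was 14.7 with LUX, against 8.37 to 11.4 in draws of regions of like width without LUX. Those draws reuse a few wide regions, as few as 1 for a match, so their range leaves out the spread between regions. Whether LUX enrichment was too low to be called at weaker ELF3 regions stays open. The median ratio of LUX to ELF3 enrichment above 1 was 0.185 in the shared regions. At that ratio LUX would be called from an ELF3 enrichment of 9.80. Of the 55 ELF3 regions at or above it, 42 held no LUX, and of the 769 below it 2 held LUX. The ratio ran from 0.116 to 0.567 over the 15 shared regions, so 9.80 is no sharp limit. It also comes from regions chosen because LUX was called there, and from lists of unlike tag extension. Of the 15 shared LUX regions, 4 were found in both calls and 11 in the main call only. Uptake of open chromatin whatever the antibody stays open, because no precipitation from untagged plants, or from plants lacking ELF3, was analysed here. The 809 ELF3 regions without LUX do not decide it for the 15 that held LUX, and joint presence of both proteins is untested.

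The second pattern is the 162 LUX regions without ELF3. Raised wild-type input cannot be told apart, because all were called against this same input, so that LUX lies above it by selection: in 64 the background was the caller's genome-wide one, itself 1.75 times the mean over the span of the chromosomes, and in the other 98 it was a median of 1.16 times (highest 3.26 times) that genome-wide one, with LUX tags at a median of 3.97 times. Of the 162, 68 were found in both calls and 94 in the main call only. Random location with respect to ELF3 is not excluded, since the median distance of their 115 loci to ELF3, 295.8 kb, lay within 95% of 1000 placements (244.2 to 476.3 kb); with each of the 162 regions counted separately, although parts of a locus are not separate places, it was 448.0 kb (267.4 to 458.3 kb, one-sided p = 0.033 by permutation of positions). Extra sequence copies in the tagged line that the wild-type input lacks, or background of the anti-MYC antibody, could give such loci and cannot be told apart from LUX sites without ELF3, because no input or untagged control of that line was analysed here.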

How the results depend on the processing

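Moving all LUX regions of a chromosome together, taking only LUX regions at the genome-wide background, pairing main LUX regions with the other ELF3 call, and joining regions within 5 kb were chosen after seeing the data. The overlap of LUX with ELF3 stayed above the placements (permutation of positions, p = 1e-04) with 50% of the shorter region required (15 regions), with summits within 200 bp (14), with both lists at or above their median fold (7 of 89), in the other peak call (4 of 91), with regions moved together (15), at genome-wide background only (9 of 73), against the other ELF3 call (15) and with LUX regions joined (15 of 130). It was 0 of 177, and so below the placement mean of 0.0391, when 50% of both regions had to overlap, which the narrow LUX regions in wide ELF3 regions preclude, and 0 of 7 with a −log10 q of at least 10, where few LUX regions are left. The difference in median ELF3 enrichment between regions with and without LUX was positive (permutation p = 1e-05) in each of its alternatives, from 9.95 to 12.7 in fold, with 10.8 for joined ELF3 regions, and 164.6 in −log10 q. The other call gave 91 LUX regions in place of 177, a summit distance of 81.5 bp in place of 42 and 3 in place of 8 of the strongest 15 ELF3 regions with LUX; the cause was not tested beyond the change of fragment length. Joining regions within 5 kb changed neither the direction nor the side of the threshold of the LUX enrichment, background and density tests. No replicate could be left out, and alternatives that need genes, promoters or sequence were not run. LUX regions rest on 33 to 87 tags at the summit and ELF3 regions on 39 to 338, which sets the width of the counting intervals.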

Other observations

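The comparisons in this part were all chosen after the data were seen. Of the 15 ELF3 regions with LUX, 14 (93.3%) had another ELF3 region within 5 kb, against 473 of the 809 (58.5%) without LUX. All 15 held several summits, against 225 of the 809 (27.8%). The 15 were also stronger and wider than the 809, with medians of 14.7-fold and 3005 bp against 3.13-fold and 401 bp. Neither trait was separated from the strength and width of the ELF3 regions, so neither can be tied to LUX. Of the 3 longest ELF3 domains, on chromosomes 3, 9 and 1, each held 1 LUX region. The fourth, on chromosome 7 from 28727269 to 28738096 with 8 ELF3 regions and an enrichment up to 9.96, held none. Chromosome 1 carried 4 of the shared regions and chromosome 9 carried 3, whereas chromosomes 2, 4, 5, 6 and 7 carried 0, with 43 to 102 ELF3 regions each. These differences were not tested.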
